A study of Mus musculus with 6 samples.

How the data were processed

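Poly-T selected messenger RNA of 6 libraries of mouse ID8-KMF ovarian cancer cells was sequenced on an Illumina HiSeq instrument after library preparation with a NEBNext Ultra kit, per the labels. Of these, 3 came from Rgnef knockout cells and 3 from knockout cells re-expressing GFP-Rgnef, and groups and replicate numbers were taken from the sample labels. The authors deposited 1 table of FPKM values with 35275 Ensembl gene identifiers and 6 libraries. FPKM stands for fragments per kilobase of transcript, scaled to a depth per library. The submitters' processing notes named the tools CASAVA 1.8, TopHat2 2.0.9 and DESeq2 and the genome build mm10. Which tool made which value, the gene annotation and the handling of strand were not given in the sources used here. Symbols and coordinates came from GENCODE mouse release M 21 (GRCm38, the same assembly as mm10), which matched 34490 identifiers and left 785 without a symbol. In all, 15620 genes were at 0 in every library.

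The low values showed that whole reads had been counted. For each of the 19655 genes above 0 a length was found that made all its values whole numbers of reads within 0.02, namely the annotated exon length for 5546 genes and the smallest such length for 14109. The implied depths were 15898965 to 17977069 reads per library, and the recovered reads summed to 99.99% to 100.06% of them. The depth used for scaling was thus close to the sum of the reads counted in genes. Counting error is larger, relative to the value, for genes with few reads.

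The test was limma 3.58.1 with trend in R 4.3.3 on log2(FPKM + 1), over genes with a mean FPKM of at least 0.5, with Benjamini-Hochberg adjustment and a call at adjusted p below 0.05. All differences are knockout minus GFP-Rgnef. A call by at least 2-fold needed a log2 difference of at least 1 in size. For this work 31 gene lists were fixed, and the 29 with at least 5 measured members were tested with camera in limma, with a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated within each list. Members called were counted over all genes and adjusted over the list alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

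Named genes followed a rule: Arhgef28, Myc and Ptk2, then the 10 genes with the largest positive and the 10 with the largest negative difference among called genes with a mean FPKM of at least 5 in the higher group, no overlap between the groups' libraries and a symbol that is not a clone, pseudogene, Gm number or accession. From each list up to 4 members followed, those called with the smallest p, filled up to 2 with the most abundant members where fewer were called. List members named without values were chosen after their values were seen. Of 120 distinct genes under the rule, 12 had exons overlapping another gene at 10% or more of their own level, and without strand such reads cannot be told apart.

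On simulated data with 200 genes changed by known folds, limma recovered 83.6% of genes changed 1.5-fold, 88.1% changed 2-fold and 98.5% changed 4-fold, with 10 false calls among 11484 genes. Of 100 random lists of 35 genes camera called 0, and it called a list lowered 1.5-fold. The simulated genes varied independently, while the estimated correlation within the real lists reached 0.54. The simulation therefore does not show how often camera calls correlated lists falsely. All simulated genes also had the same dispersion (0.00642), and no deviation was shared between libraries. The recovery and false calls of limma hold for that setting and may differ for real genes that vary more. Alternatives covered the pseudocount, the filter, scaling, the variance model, the replicate number as a block, each library left out, the set test, reads recovered from FPKM tested with voom in limma, chromosomes 7 and 9, and the libraries numbered 3. All columns of the table were used. Some genes and 2 of the tested lists enter the counts but are not reported here.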

Results

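Messenger RNA was profiled in ID8-KMF cells, a mouse ovarian cancer line obtained by passaging ID8 cells in mice. In the cells of all 6 libraries the Rgnef gene (Arhgef28), which encodes a guanine nucleotide exchange factor, had been knocked out. In 3 of the 6 libraries the knockout cells carried a lentivirus expressing GFP-tagged Rgnef, and these are called GFP-Rgnef libraries here. The other 3 came from knockout cells without the construct. Both kinds of cell were grown subconfluent on dishes seeded with Matrigel, and the comparison asks which transcripts differ with the presence of GFP-Rgnef. The lentivirus and the GFP tag came with Rgnef, so their effects cannot be told apart from those of Rgnef. The unedited parental line was not part of the series, so every difference below is knockout against re-expression. The deposited FPKM values implied depths of 15898965 to 17977069 reads per library, and 10572 to 10756 genes had an FPKM of at least 1. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

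Rgnef RNA matched the labels in all 6 libraries. Arhgef28 (ENSMUSG00000021662, GRCm38 chromosome 13, 97899469 to 98206439, minus strand, protein coding) stood at 52.7 ± 3.93 FPKM (SD, n = 3) in the GFP-Rgnef libraries. In the knockout libraries it stood at 0.1198 ± 0.0123 FPKM (SD, n = 3), from 12 to 14 reads per library against 5067 to 6095. The fitted difference was -5.58 (SE 0.089, limma adjusted p = 3.02e-08) on the log2(FPKM + 1) scale, which understates the change of low genes. Reads of the re-expressed construct and of the endogenous gene were not separated. Both groups are knockout cells, and those without the construct had only 12 to 14 reads. If the endogenous level was alike in both, nearly all reads of the GFP-Rgnef libraries came from the construct. The difference then measures its expression and not the loss of endogenous RNA. Myc and Ptk2, the focal adhesion kinase gene, did not pass the test: Myc differed by -0.36 (SE 0.112) and Ptk2 by 0.05 (SE 0.059), with limma adjusted p of 0.07 and 0.655.

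**Figure D1:**
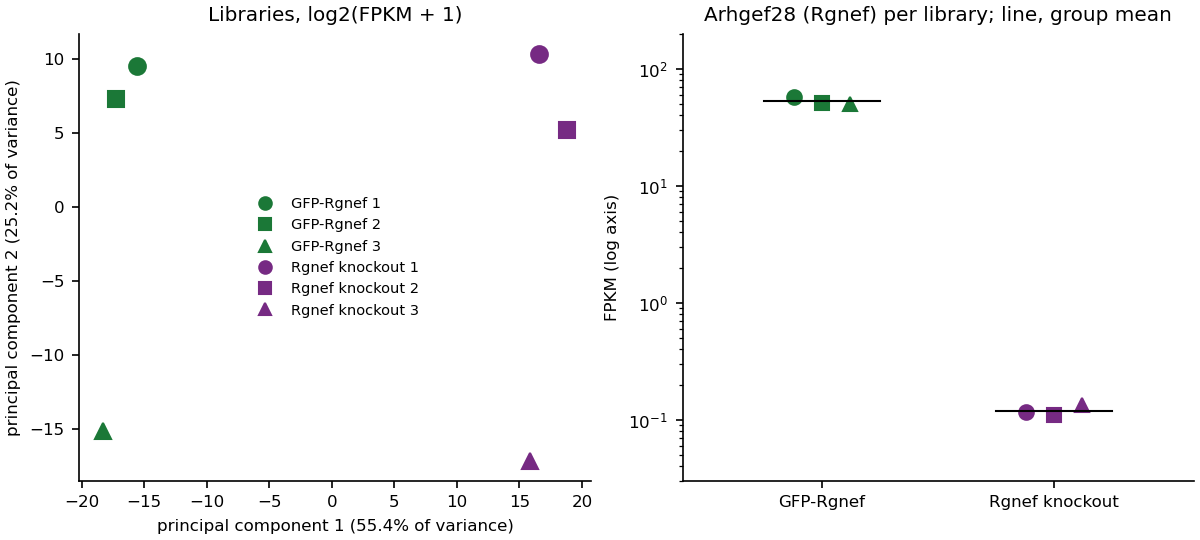
Left, the 6 libraries on the first and second principal components of log2(FPKM + 1), coloured by group and shaped by replicate number. Right, Arhgef28 in FPKM per library on a log axis, with a line at the group mean. Component 1 (55.4% of the variance) separates knockout from GFP-Rgnef libraries, component 2 (25.2%) separates the libraries numbered 3 from the others, and Arhgef28 lies at 50.02 to 57.24 FPKM against 0.110 to 0.134.

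The knockout libraries had higher RNA of 925 genes and lower RNA of 614 genes among the 11500 tested (limma, adjusted p below 0.05). By at least 2-fold, 114 genes rose and 60 fell. These 2 numbers were 217 and 104 with a pseudocount of 0.1, 231 and 105 by voom on recovered reads, and 48 and 29 at a mean FPKM of at least 5, and 34 fell without knockout 2. The group that rose most was led by Col5a2, a chain of type V collagen, which went from 0.233 ± 0.146 FPKM in GFP-Rgnef libraries to 21.7 ± 4.11 in knockout libraries (SD, n = 3). Hs6st2, a heparan sulfate sulfotransferase, rose from 1.64 ± 0.254 to 20.04 ± 0.415 FPKM, and Dse, a dermatan sulfate epimerase, from 0.610 ± 0.128 to 6.04 ± 1.14. Slit2, a secreted guidance ligand, rose from 0.387 ± 0.127 to 9.92 ± 2.15 FPKM. Gdf6, a ligand of the bone morphogenetic protein family, went from 5.89 ± 2.37 to 42.8 ± 16.6, and Inhba, the activin A subunit, from 5.66 ± 1.22 to 28.9 ± 1.54. Vgll3, a cofactor of TEAD transcription factors, rose from 0.354 ± 0.175 to 6.001 ± 0.801 FPKM, and the retinaldehyde dehydrogenase gene Aldh1a1 from 2.28 ± 0.741 to 13.4 ± 0.271. Cryab, a small heat shock protein on chromosome 9, rose from 3.002 ± 0.284 to 18.5 ± 0.491, and Vat1l from 8.10 ± 3.24 to 45.2 ± 17.0. On the log2 scale these 10 genes differed by 2.12 to 4.19, with limma adjusted p from 4.79e-06 to 0.00529.

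Among the genes that fell most were enzymes that detoxify aldehydes and electrophiles. Aldh3a1, an aldehyde dehydrogenase, fell from 63.4 ± 34.7 FPKM with GFP-Rgnef to 2.89 ± 1.25 without it (log2 difference -3.97, SE 0.351, limma adjusted p = 0.000614). Gsta1, a glutathione transferase, fell from 48.8 ± 27.4 to 2.97 ± 0.915 FPKM, although its reads are uncertain because the gene has near-identical copies. Cbr3, a carbonyl reductase, fell from 19.2 ± 5.27 to 3.62 ± 0.884 FPKM, and Slc7a11, the cystine and glutamate exchanger, from 9.83 ± 6.29 to 1.86 ± 0.669. For Aldh3a1, Gsta1, Cbr3 and Slc7a11 the GFP-Rgnef library numbered 3 was the highest, for Slc7a11 at 17.1 FPKM against 6.27 and 6.13. Eya2, a transcriptional cofactor, dropped from 14.0 ± 0.852 to 1.57 ± 0.0704 FPKM, and Arhgap40 from 5.17 ± 0.720 to 0.233 ± 0.127. Epb41l4b, a FERM domain protein, fell from 61.1 ± 9.96 to 15.6 ± 1.38, and Pappa, a protease of insulin-like growth factor binding proteins, from 10.6 ± 2.26 to 2.89 ± 1.17. The serine protease gene Htra3 fell from 14.2 ± 3.77 to 4.50 ± 0.740 FPKM. Lgals2, a galectin, had 20.7 ± 5.42 against 6.29 ± 2.39 FPKM, but its exons overlap the more abundant Cdc42ep1 on the opposite strand and the kit named in the labels is not described as strand-specific. These 10 genes differed by -3.97 to -1.45 on the log2 scale, with limma adjusted p from 7.05e-06 to 0.0132.

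**Figure D2:**
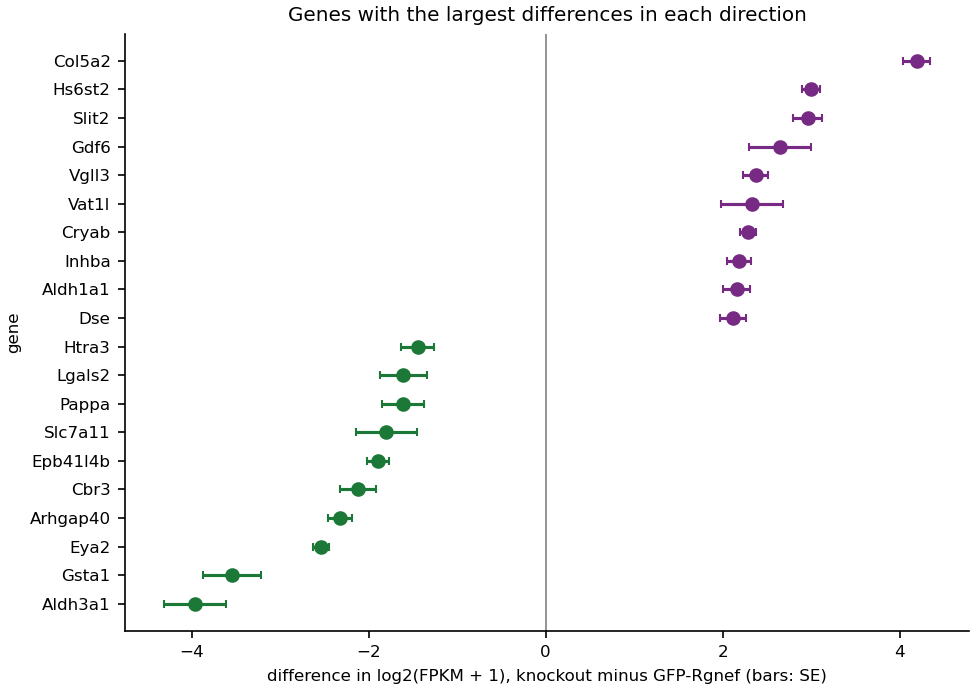
Difference in log2(FPKM + 1), knockout minus GFP-Rgnef, with the standard error of the limma fit as bars (3 libraries per group), for the 10 genes with the largest positive and the 10 with the largest negative difference under the rule for named genes. Col5a2 lies highest at 4.19 and Aldh3a1 lowest at -3.97.

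The tested genes include 3838 (33.4%) whose 3 knockout libraries all lay on one side of the 3 GFP-Rgnef libraries, where chance gives 10%. The libraries numbered 3 stood apart from the others in both groups, on component 2. With only the libraries numbered 1 and 2 of each group, 1273 genes rose and 1048 fell. Leaving out the library numbered 1 or 2 of either group lowered the counts to 455 to 592 higher and 198 to 378 lower. Without a filter on low values 394 fell. With 1 of the 6 libraries left out, Slc7a11 was the only one of the 20 genes with the largest differences to lose its call (without knockout 2, limma adjusted p = 0.0631). Among the other genes that are named below and follow the rule for named genes, those that lost their call without at least 1 library were Atp5o, Axl, Bst2, Cav1, Ccnb2, Cyp51, Dcn, Dhcr7, Fabp4, Fbl, Fzd2, Hsp90b1, Ifih1, Itga3, Kif23, Ldha, Manf, Ndufb7, Nfe2l2, Nop56, Nr2f2, Por, Prc1, Psph, Sc5d, Slc40a1, Tjp1, Ttk and Uqcrq, with limma adjusted p up to 0.159.

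Genes on chromosomes 7 and 9 were higher together in the knockout libraries. On chromosome 7, 236 of 819 tested genes rose and 7 fell, with a median log2 difference of 0.25. On chromosome 9, 234 of 639 rose and 8 fell, with a median of 0.28. The medians of all other chromosomes lay between -0.07 and 0.03. Chromosomes 7 and 9 held 12.7% of the tested genes but 50.8% of those that rose and 2.4% of those that fell. Elsewhere, 455 genes rose and 599 fell. Among genes with a mean FPKM of at least 10, the median ratio relative to the other chromosomes was 1.25 for chromosome 7 and 1.27 for chromosome 9. Each knockout library had a positive median deviation on both chromosomes (0.108 to 0.152) and each GFP-Rgnef library a negative one (-0.163 to -0.096). Camera called chromosomes 7 and 9 higher with adjusted p of 3.14e-26 and 1.28e-30, and both calls held with a correlation estimated within the chromosome (adjusted p = 0.0353 and 0.00302). With the preset correlation camera also called chromosomes 4, 8, 11 and 17 (medians -0.069 to -0.061) and X (median 0.034), with adjusted p from 0.0105 to 0.0211. None of these calls held with an estimated correlation (camera adjusted p from 0.182 to 0.459). On the X chromosome, 27 of 60 tested genes between 133582860 and 152342425 (GRCm38) rose and 1 fell, with a median of 0.327. These bounds were chosen after the values were seen, as those of the 3 windows of X with the highest medians. Removing each chromosome's median deviation from each library left 495 genes higher and 388 lower. Of the genes under the rule for named genes, 23 lost their call by this and 2 more changed sign. With chromosomes 7 and 9 left out, 45.5% of the calls were higher, against 60.1% with them.

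**Figure D3:**
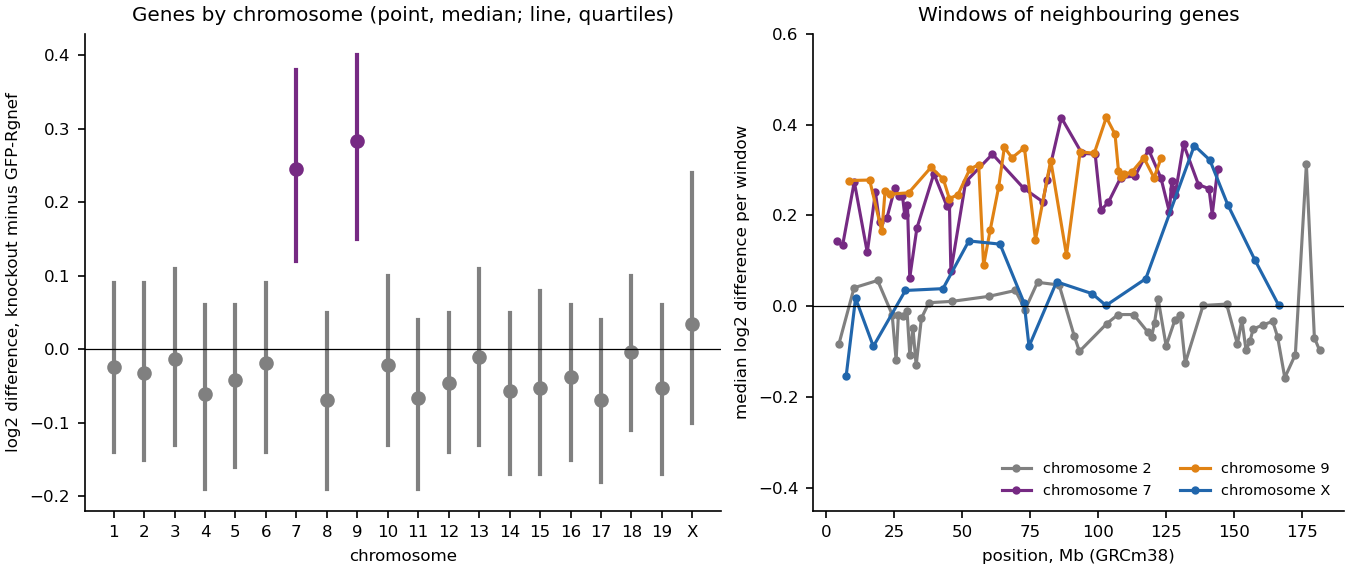
Left, the median (point) and quartiles (line) of the log2 difference, knockout minus GFP-Rgnef, over the tested genes of each chromosome. Right, the median difference in windows of 20 neighbouring tested genes along chromosomes 2, 7, 9 and X against position in Mb (GRCm38). Chromosomes 7 and 9 have medians of 0.25 and 0.28, with 0 of 73 windows at or below 0, and the segment of X chosen for its high windows has a median of 0.327.

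Targets of NRF2, the transcription factor of the response to oxidants and electrophiles, fell together in the knockout libraries. Of 37 measured members 17 fell and 0 rose (23 fell adjusted over the list alone), with a median log2 difference of -0.46, and 4 of the 17 lie on chromosome 9 or 7, where most other calls were higher. Beside Gsta1 and Cbr3, Slc6a9, a glycine transporter, fell from 15.5 ± 1.39 to 7.49 ± 0.883 FPKM, and G6pdx, the first enzyme of the pentose phosphate pathway, from 208.4 ± 11.1 to 150.3 ± 2.21 (SD, n = 3). Exons of Slc6a9 and G6pdx overlap expressed genes on the opposite strand. Camera called the list lower with an adjusted p of 2.39e-10, and with an adjusted p of 0.51 with an estimated correlation it was not called. The number that fell was 11 without knockout 2 and 11 of 29 with chromosomes 7 and 9 left out. Within each group the library numbered 3 had higher values of this list than the other libraries, by a median of 0.37 with GFP-Rgnef and 0.18 without. Nfe2l2, which encodes NRF2 itself, fell from 112.3 ± 2.45 to 87.9 ± 4.86 FPKM.

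Antioxidant enzymes went both ways. Of 46 measured members 8 rose, 5 of them on chromosome 7 or 9, and 11 fell (11 and 15 adjusted over the list alone), and camera did not call the list (adjusted p = 0.315). Its median was -0.14 and its mean -0.01. The numbers that rose and fell were 5 and 7 without GFP-Rgnef 1, 4 and 4 without GFP-Rgnef 2 and 3 and 7 after chromosome centring, 5 fell without knockout 1, without knockout 2 or without a filter, and 2 of 39 rose with chromosomes 7 and 9 left out. Sod1, the cytosolic superoxide dismutase, fell from 377.5 ± 24.4 to 265.0 ± 10.1 FPKM, and Gss, glutathione synthetase, from 43.3 ± 1.12 to 25.7 ± 2.39. Msrb3, a methionine sulfoxide reductase, rose from 5.91 ± 0.151 to 21.1 ± 3.19, and the kinase gene Oxsr1 on chromosome 9 from 42.1 ± 1.05 to 58.7 ± 2.62. Of 26 ferroptosis regulators 4 fell and 1 rose, the same numbers as adjusted over the list alone (camera adjusted p = 0.304). Of this list 1 fell without GFP-Rgnef 2 or knockout 2, 2 fell without knockout 3, without a filter, without limma's trend, with TPM scaling or after chromosome centring, and at most 2 rose with any 1 library left out. Those that fell were Slc7a11, Nfe2l2, the lipid peroxidase gene Gpx4 and Por, a cytochrome P450 reductase with 120.2 ± 8.01 against 96.3 ± 6.497 FPKM, and the one that rose was the iron exporter gene Slc40a1, from 0.818 ± 0.175 to 2.09 ± 0.562.

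NF-kB targets were lower in knockout libraries, with 12 of 39 measured members falling and 3 rising (14 and 3 adjusted over the list alone) and a median of -0.26. Nfkbia, the inhibitor of NF-kB that it induces, fell from 33.7 ± 0.668 to 22.6 ± 1.83 FPKM, and the chemokine gene Cx3cl1 from 9.16 ± 1.62 to 3.84 ± 0.640. Members that rose were Vcam1, Csf1, the macrophage growth factor, from 71.0 ± 6.18 to 120.6 ± 10.1, and the adhesion molecule gene Icam1 on chromosome 9, from 2.37 ± 0.460 to 5.26 ± 0.310. Camera gave an adjusted p of 0.0134 for the list, and an adjusted p of 0.51 with an estimated correlation. The number of members that fell dropped to 4 without GFP-Rgnef 1, 3 without GFP-Rgnef 2, 6 without knockout 1, 3 without knockout 2 and 5 without a filter on low values, while camera's adjusted p with 1 library left out stayed between 0.00307 and 0.0262. Among 23 immediate early genes 1 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.108): Ier3, from 146.5 ± 12.3 to 92.5 ± 5.25 FPKM. Without knockout 3, 5 fell. In the interferon response 3 of 21 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.484). Bst2, Ifih1 and Ifit2 rose, the last from 0.203 ± 0.0251 to 2.52 ± 0.117 FPKM, while Oasl1 fell from 33.2 ± 2.53 to 21.6 ± 1.64. Without GFP-Rgnef 1 or knockout 1, 1 of this list rose, and 2 fell without knockout 1.

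Nuclear genes for oxidative phosphorylation were lower by a small amount, with 8 of 50 falling and 3 rising (14 and 3 adjusted over the list alone) and a median of -0.15. All 3 that rose, Sdhd, Uqcrc1 and Uqcrc2, lie on chromosome 7 or 9. Ndufb7 of complex I fell from 26.9 ± 0.460 to 20.9 ± 0.587 FPKM, Uqcrq of complex III from 208.1 ± 5.79 to 173.7 ± 4.29, and Atp5o of the ATP synthase from 122.3 ± 1.49 to 101.6 ± 1.97. Camera gave an adjusted p of 0.000176 and, with an estimated correlation, an adjusted p of 0.51. With any 1 library left out at most 1 member rose. At most 1 fell without GFP-Rgnef 1, GFP-Rgnef 2, knockout 1 or knockout 2, while 8 fell without GFP-Rgnef 3 and 9 without knockout 3, and 2 fell after each chromosome's median deviation was removed. Camera's adjusted p with 1 library left out lay between 2.33e-05 and 0.00695. Of 12 measured mitochondrially encoded transcripts, 0 passed limma's test, also adjusted over the list alone, 1 at an unadjusted p below 0.05 and 1 by voom on recovered reads (median -0.10, camera adjusted p = 0.255). Within each group the library numbered 3 had higher values of this list, by a median of 0.22 with GFP-Rgnef and 0.04 without, and 1 member fell without knockout 1. Among them mt-Co1 had 3117 ± 203 FPKM with GFP-Rgnef and 2387 ± 370 without (limma adjusted p = 0.0571).

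Extracellular matrix genes were higher without GFP-Rgnef. Of 34 measured, 10 rose, 3 of them on chromosome 7 or 9, and 3 fell (14 and 3 adjusted over the list alone), with a median of 0.32. Those that fell included Dcn and Fbln1. Beside Col5a2, the collagen cross-linking enzyme genes Lox and Loxl1 rose from 11.4 ± 0.845 to 31.2 ± 1.19 and from 59.7 ± 7.004 to 118.9 ± 10.8 FPKM. The basement membrane collagen gene Col4a1 rose from 60.2 ± 6.01 to 88.6 ± 5.55, and its exons overlap Col4a2 on the opposite strand. Camera called the list higher (adjusted p = 0.000139), with an adjusted p of 0.18 with an estimated correlation. With chromosomes 7 and 9 left out 5 of 31 rose, and 1 fell without any 1 library other than GFP-Rgnef 3. Of 19 mesenchymal transition markers 3 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 0.00148, and adjusted p = 0.18 with an estimated correlation). These were Lox, Cdh2 (N-cadherin), which went from 10.1 ± 1.07 to 44.2 ± 0.279 FPKM, and the receptor kinase gene Axl on chromosome 7, from 297.6 ± 17.0 to 404.5 ± 37.6. Without knockout 3, 6 of these markers rose and 1 fell. Among 24 matrix proteases and their inhibitors 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.255). Timp3, a metalloprotease inhibitor, rose from 160.5 ± 15.4 to 266.4 ± 30.8 FPKM, and the cathepsin gene Ctsl from 53.7 ± 11.8 to 110.7 ± 16.3. Adam10 and Adamts5 rose too, and Mmp24, whose exons overlap an antisense gene, was the one that fell.

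Growth factors and their receptors rose in 8 of 37 cases and fell in 3 (9 and 4 adjusted over the list alone), with a median of 0.20. Met, the receptor of hepatocyte growth factor, rose from 51.9 ± 1.00 to 77.6 ± 1.84 FPKM, and Vegfc, a lymphatic growth factor, from 3.76 ± 0.174 to 6.65 ± 1.01. Vegfa and Gdf15 fell, and Tgfa, a ligand of the epidermal growth factor receptor, went from 11.7 ± 0.663 to 7.92 ± 0.226. Camera called the list higher (adjusted p = 0.0143), with an adjusted p of 0.18 with an estimated correlation. Without GFP-Rgnef 2, 4 rose and 1 fell, and 1 fell without knockout 1 or knockout 2.

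Genes of the actin cytoskeleton and targets of SRF rose in 7 of 29 cases and fell in 0 (8 and 0 adjusted over the list alone), with a median of 0.12, and 3 of the 7 lie on chromosome 7 or 9. Fhl1, a LIM domain protein, rose from 1.94 ± 0.309 to 8.41 ± 0.332 FPKM, Zyx (zyxin) from 83.6 ± 5.57 to 113.1 ± 5.90, and Tpm1 (tropomyosin, on chromosome 9) from 423.3 ± 10.3 to 602.0 ± 18.8. The matrix glycoprotein gene Thbs1 rose from 4.31 ± 0.540 to 8.41 ± 1.52. Camera called the list higher (adjusted p = 0.000378), with an adjusted p of 0.18 with an estimated correlation, and 4 of 25 rose with chromosomes 7 and 9 left out. Targets of the coactivators YAP and TAZ rose in 8 of 29 cases, 4 of them on chromosome 7 or 9, and fell in 1, Ccn1 (11 and 2 adjusted over the list alone; median 0.11). Besides Inhba, Edn1 (endothelin) rose from 5.90 ± 1.99 to 18.1 ± 4.66 FPKM, Amotl2 on chromosome 9 from 133.2 ± 31.1 to 270.7 ± 42.4 and Tead1 on chromosome 7 from 69.7 ± 1.18 to 109.9 ± 8.12. Camera gave an adjusted p of 0.00965, and an adjusted p of 0.18 with an estimated correlation. The number that fell was 3 without knockout 3, and the number that rose was 4 without GFP-Rgnef 2, 5 without knockout 2 or after chromosome centring, and 2 of 24 with a median of 0.005 when chromosomes 7 and 9 were left out.

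Integrin and focal adhesion genes rose in 5 of 28 cases, 2 of them on chromosome 7 or 9, and fell in 1, also adjusted over the list alone (camera adjusted p = 0.455). Tln2, Zyx and Itgb5 rose, as did Cav1 (caveolin), from 346.5 ± 29.3 to 469.8 ± 28.5 FPKM and Parva on chromosome 7 from 61.0 ± 2.34 to 86.3 ± 2.67, while Itga3, an integrin chain, fell from 469.1 ± 35.3 to 342.6 ± 31.2. Without GFP-Rgnef 2 or knockout 1 and with chromosomes 7 and 9 left out 3 rose, 2 fell without knockout 1, and the fall of Itga3 was not called without GFP-Rgnef 1, GFP-Rgnef 2 or knockout 2.

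**Figure D4:**
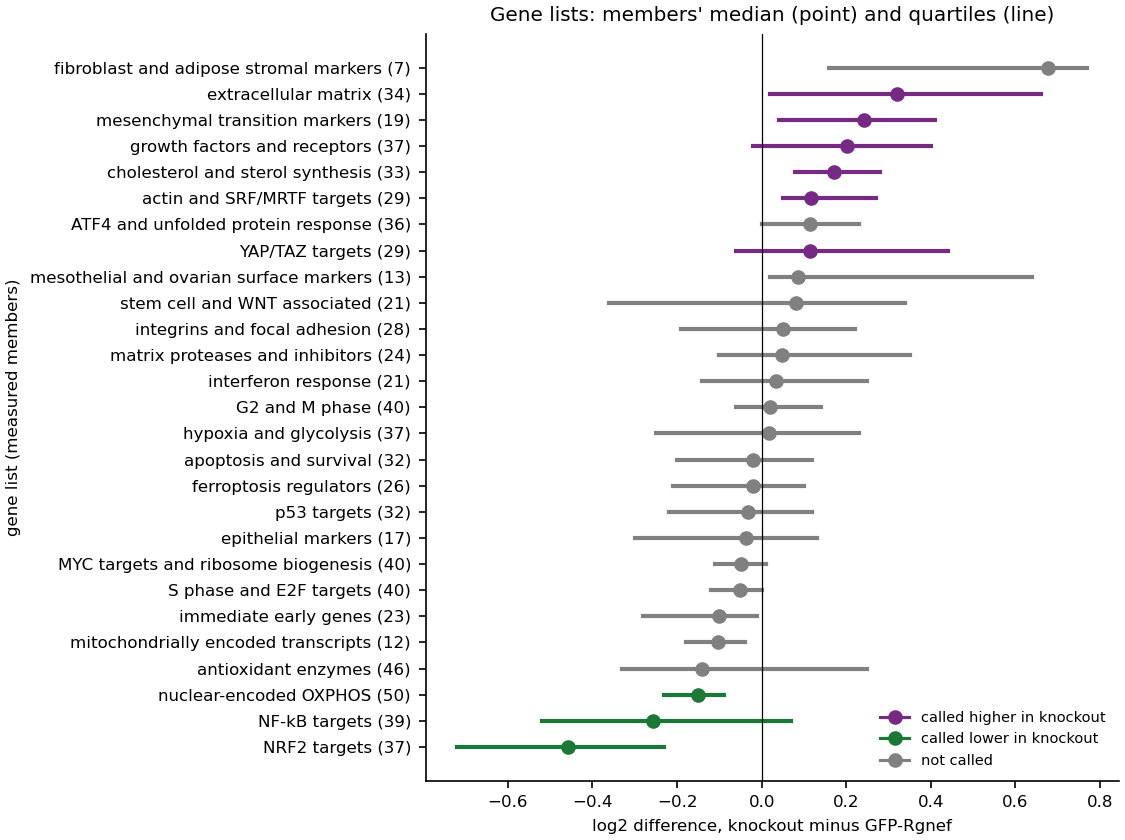
Median (point) and quartiles (line) of the log2 difference, knockout minus GFP-Rgnef, over the measured members of the 27 tested lists reported here, with the number of members in brackets and colour for the camera call with the preset correlation. The called lists run from NRF2 targets at -0.46 to extracellular matrix at 0.32.

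**Figure D5:**
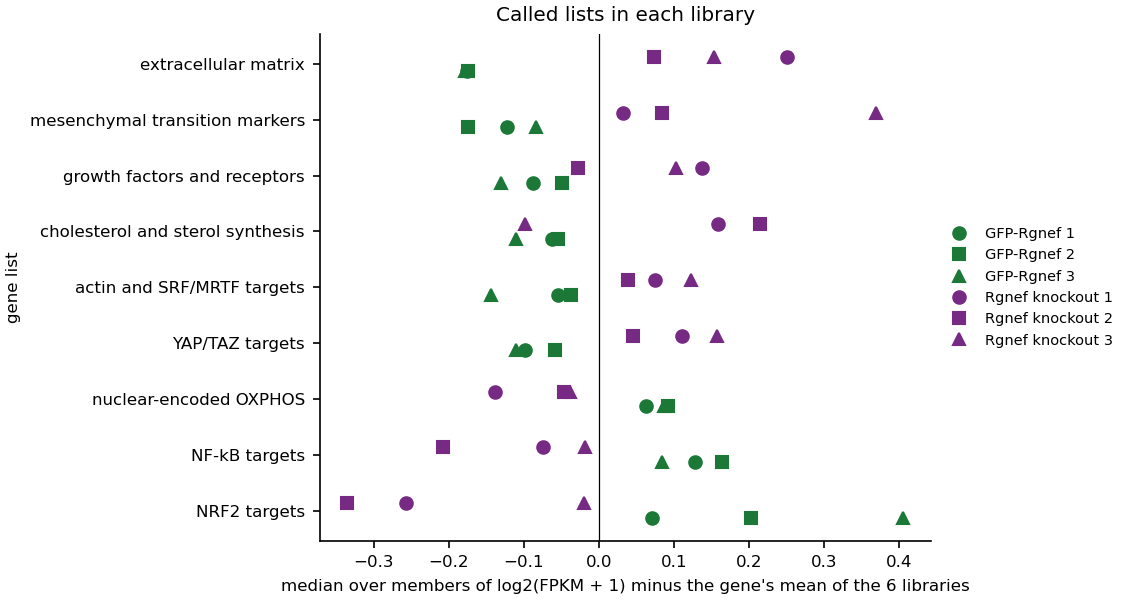
For each of the 9 called lists reported here and each of the 6 libraries, the median over members of log2(FPKM + 1) minus the gene's mean over the 6 libraries. NRF2 targets lie at 0.070, 0.202 and 0.405 in the GFP-Rgnef libraries and at -0.257, -0.335 and -0.020 in the knockout libraries, with the library numbered 3 highest in each group.

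Sterol synthesis genes rose in 5 of 33 cases, 2 of them on chromosome 7 or 9, and fell in 0, also adjusted over the list alone, with a median of 0.17. Idi1 and Sc5d were among them. Acat2 rose from 19.9 ± 0.819 to 30.0 ± 3.26 FPKM, and Dhcr7 on chromosome 7 from 25.1 ± 4.01 to 34.8 ± 3.38. Cyp51, with 49.6 ± 1.26 against 63.5 ± 5.6 FPKM, overlaps Akap9 on the opposite strand. Camera called the list higher (adjusted p = 0.00206), with an adjusted p of 0.59 with an estimated correlation. The number that rose was 2 without GFP-Rgnef 1, 1 without GFP-Rgnef 2, 3 without GFP-Rgnef 3, 3 without knockout 1, 1 without knockout 2 and 8 without knockout 3, and 2 without a filter, after chromosome centring or with chromosomes 7 and 9 left out. In both groups the library numbered 3 had lower values of this list, with median differences of -0.09 with GFP-Rgnef and -0.26 without. Of 36 genes of the ATF4 and unfolded protein responses 3 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.108), namely Psph, the chaperone gene Hsp90b1, from 382.0 ± 4.12 to 456.2 ± 35.2, and Manf on chromosome 9, from 151.0 ± 18.7 to 231.1 ± 34.7. With the preset correlation camera called this list under 7 alternatives, with adjusted p from 0.00132 without knockout 3 to 0.689 without GFP-Rgnef 3, and with all 6 libraries it had an adjusted p = 0.76 with an estimated correlation. At most 1 of its members rose without any 1 library other than knockout 3. Psph and Manf have exons overlapping other expressed genes, and Slc7a11 was the one that fell. Hypoxia and glycolysis genes rose in 6 of 37 cases and fell in 5 (7 and 7 adjusted over the list alone; camera adjusted p = 0.803). The lactate transporter gene Slc16a3 rose from 8.10 ± 0.999 to 19.4 ± 2.41 FPKM and the glucose transporter gene Slc2a1 fell from 71.6 ± 1.14 to 52.9 ± 2.97. Hk1, Gapdh, Vegfa and Egln3 also fell. Without GFP-Rgnef 2, 3 of this list rose and 1 fell, 1 fell without knockout 2, and 3 fell without knockout 1, without knockout 3, without limma's trend or with TPM scaling, and 2 without a filter.

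Few cell cycle genes passed the test. All 5 of the 40 measured genes of the G2 and M phases that rose lie on chromosome 7 or 9, among them Prc1 (111.5 ± 4.45 to 147.0 ± 11.8 FPKM), Ttk (23.6 ± 0.833 to 30.0 ± 1.44), Ccnb2 (65.1 ± 1.74 to 79.9 ± 5.17) and Kif23 (40.2 ± 0.592 to 49.1 ± 2.67) besides Anln. Of this list 1 fell, Cdca3, also adjusted over the list alone (camera adjusted p = 0.315). At most 1 rose without GFP-Rgnef 1, GFP-Rgnef 2, knockout 1 or knockout 2, 3 rose without GFP-Rgnef 3 and 2 without limma's trend, and the fall of Cdca3 was not called with any 1 library left out. With each chromosome's median deviation removed, Ccnb2 and Kif23 differed by -0.001 and -0.013. Of 40 genes of S phase, 1 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.266): Rrm1 on chromosome 7, from 92.8 ± 0.351 to 129.5 ± 5.80. Without knockout 3, 3 rose and 1 fell. Pcna had 485.8 ± 45.4 against 450.0 ± 33.5 FPKM (limma adjusted p = 0.462). Targets of p53 rose in 3 of 32 cases, 2 of them on chromosome 7 or 9, and fell in 4, also adjusted over the list alone (camera adjusted p = 0.547). Ei24 and Aen rose, and Cdkn1a, Plk2 and Fdxr fell. In this list 2 fell without GFP-Rgnef 1, without knockout 1 or without a filter, 1 fell without GFP-Rgnef 2 or knockout 2, and 5 rose without GFP-Rgnef 3. Pmaip1 (Noxa) rose from 1.88 ± 0.533 to 4.95 ± 0.0346 FPKM and Perp fell from 94.95 ± 5.37 to 59.0 ± 7.65. Of 32 genes of apoptosis and survival 2 rose, also adjusted over the list alone, Pmaip1 and the necroptosis kinase gene Ripk3 (1.31 ± 0.173 to 3.75 ± 0.530 FPKM). Its median was -0.02 and its mean 0.03 (camera adjusted p = 0.938, higher), and 4 fell without knockout 3. MYC targets rose in 2 of 40 cases, Ldha and Fbl, both on chromosome 7, and fell in 1, Nop56 (exons overlap antisense Idh3b), also adjusted over the list alone (camera adjusted p = 0.266). With 1 library left out, at most 1 rose without any library other than knockout 1 or knockout 3, and at most 2 fell.

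With all 6 libraries and the preset correlation, camera called none of the lists of cell identity markers, but 2 of them were called under other settings. Epithelial markers rose in 3 of 17 cases and fell in 2, also adjusted over the list alone (median -0.04, mean 0.01, camera adjusted p = 0.97). Tjp1 and Krt14 rose and Elf3 fell. Without GFP-Rgnef 2, knockout 1 or knockout 2, and with chromosomes 7 and 9 left out, 1 of this list rose. Pkp1 (plakophilin) rose from 5.81 ± 0.390 to 18.9 ± 0.275 FPKM and Krt18 (keratin) fell from 319.8 ± 29.8 to 224.4 ± 9.21. Mesothelial and ovarian surface markers rose in 3 of 13 cases (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0727), and all 3, Tbx18, Bnc1 and Nr2f2, lie on chromosome 7 or 9. Camera called this list higher without GFP-Rgnef 1, without knockout 3, without a filter and after chromosome centring. It also did so with the replicate number as a block, with the libraries numbered 1 and 2 only and with a term for the libraries numbered 3. With the preset correlation its adjusted p ran from 0.00922 without knockout 3 to 0.372 with chromosomes 7 and 9 left out, and with all 6 libraries it had an adjusted p = 0.51 with an estimated correlation. Stem cell and WNT genes rose in 4 of 21 cases and fell in 3 (7 and 5 adjusted over the list alone), with a median of 0.08, a mean of -0.11 and a camera adjusted p of 0.635. Tcf7, Wnt5b, Aldh1a1 and the WNT receptor gene Fzd2 (10.2 ± 0.984 to 15.3 ± 1.41 FPKM) rose, and Aldh2, Aldh3a1 and Wnt4 (9.32 ± 2.24 to 4.46 ± 0.287) fell. Of these 2 rose without GFP-Rgnef 1, GFP-Rgnef 2, knockout 1 or knockout 2, and 5 fell without knockout 3. Fibroblast and adipose stromal markers rose in 2 of 7 cases and fell in 1 (4 and 1 adjusted over the list alone; median 0.68, camera adjusted p = 0.108). Camera called it without knockout 2 (adjusted p = 0.0262), after chromosome centring (0.0496) and with chromosomes 7 and 9 left out (0.0324), over a range of 0.0262 to 0.403 with the preset correlation. With all 6 libraries it had an adjusted p = 0.51 with an estimated correlation. Fabp4 rose, and lipoprotein lipase (Lpl) went from 3.38 ± 0.607 to 6.63 ± 0.436 FPKM and decorin (Dcn) fell from 58.9 ± 13.8 to 32.8 ± 8.32. The fall of Dcn was called without GFP-Rgnef 3 and not with any other 1 library left out, and 1 of the list rose without GFP-Rgnef 1 or GFP-Rgnef 2. Markers of leukocytes and endothelium had 3 and 4 measured members and were not tested as lists. The leukocyte markers reached at most 3.81 FPKM in any library, and 0 passed limma's test, 0 at an unadjusted p below 0.05 and 0 by voom on recovered reads. Of the endothelial markers 1 rose, Esam on chromosome 9, from 30.9 ± 3.04 to 57.9 ± 3.31 FPKM.

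Of the 29 lists tested, 7 were called higher and 3 lower by camera with the preset correlation. With an estimated correlation 0 of the 10 calls held. For actin and SRF targets, YAP and TAZ targets, mesenchymal markers and growth factors the estimates were 0.01, -0.01, 0.01 and 0. Their unadjusted camera p still rose from 5.21e-05, 0.00266, 0.000256 and 0.00491 to 0.017, 0.027, 0.02 and 0.031. With the preset at 0.01, a larger correlation does not account for the loss of these calls. Counts of single genes are not a set test, so they cannot stand in for the lost calls. List members called numbered 185 with all 6 libraries, 88 without GFP-Rgnef 2, 206 without knockout 3 and 123 after chromosome centring. Over all 11500 tested genes, 925 rose and 614 fell. Other splits of the 6 libraries into 3 and 3 called up to 11 lists with the preset correlation.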

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

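The test, the filter, the lists, the rule for named genes and the alternatives for pseudocount, filter, scaling, variance model, block, left-out libraries and set test were fixed before the data were examined. The alternatives with voom, with chromosomes 7 and 9 left out or centred, with only the libraries numbered 1 and 2, and with a term for the libraries numbered 3 were chosen after seeing the data. The planned edgeR quasi-likelihood and DESeq2 tests on recovered reads were not run. Over all settings the named genes kept direction and call in 2392 comparisons, lost the call in 160 and gained it in 13, and an uncalled value that changed sign counts as kept. Lists kept their call or lack of it in 613 and gained one in 24, of which the mesothelial and the ATF4 lists each gained 7, both also under the block (camera adjusted p = 0.0289 and 0.0122, against adjusted p = 0.51 and 0.76 with an estimated correlation and no block), fibroblast markers 3, MYC targets 2, immediate early genes 2, and G2 and M phase genes and matrix proteases 1 each. Arhgef28 stayed called and lower under every setting that fitted genes. Chromosome centring by construction removes the shift of a gene's chromosome. Under it the differences of Ccnb2 (-0.001) and Kif23 (-0.013) vanished, and these 2, with a changed sign, are not among the 160. A further 23 named genes lost their call under centring. It left 495 genes called higher and 388 lower, and 123 list members called. With chromosomes 7 and 9 left out, fewer genes were tested, and 393 were higher with 108 list members. A pseudocount of 0.1, which shrinks low genes less, gave 217 higher and 104 lower by at least 2-fold, and voom gave 231 and 105. No filter left 394 lower, with more genes tested. A mean FPKM of at least 5 left 48 higher and 29 lower by at least 2-fold, with fewer genes tested. Leaving out 1 library, hence with fewer samples, gave 455 to 850 higher, 198 to 578 lower, 34 to 71 lower by at least 2-fold, and 88 to 206 list members. The counts moved most without GFP-Rgnef 1 (512 higher, 305 lower), GFP-Rgnef 2 (455, 198), knockout 1 (592, 378) and knockout 2 (492, 214). They fell less without GFP-Rgnef 3 (839, 530) or knockout 3 (850, 578), so fewer samples alone do not account for the drop. With only the libraries numbered 1 and 2 there were 1273 higher, 1048 lower and 292 list members. With a term for the libraries numbered 3 there were 1653, 1450 and 361. Both settings take the shared deviation of the libraries numbered 3 out of the residual spread, and other causes were not tested. The numbers 1 and 2 did not pair the libraries. Their deviations correlated between groups at 0.32 and -0.02 with the same number and at 0.4 and 0.29 across the numbers. The libraries numbered 3 did go together, at 0.55. As a replicate block the numbers gave 1517 higher, 1253 lower and 335 list members. The block also takes the shared deviation of the libraries numbered 3 out of the residual spread, and other causes were not tested. With an estimated correlation 0 lists were called, and fry, which does not compare a list with other genes, called 27 for change in either direction and 7 for a shared direction, none of them the 3 lists that camera called lower (adjusted p = 0.0537 each). The lowest correlation within a group and the highest between groups were 0.9844 and 0.9788 with a pseudocount of 0.1, and 0.9869 and 0.9827 at a mean FPKM of at least 5, against 0.9903 and 0.9872; the cause was not tested. Simulated 1.5-fold changes were recovered in 83.6% of genes over all levels and 92.3% at a mean FPKM of at least 5; depth and the pseudocount both bear on low genes and were not separated.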

Other observations

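The tests of copy number, of chance deviation of single libraries, of depth and of NRF2 targets without the libraries numbered 3 were chosen after the result was seen, and the genes named in the next sentences were chosen after their values were seen. The libraries numbered 3 of both groups shared a pattern of their own. The contrast of the libraries numbered 3 with the others was formed because they stood apart in these same values. Many of its limma and camera calls were thus given beforehand, and their adjusted p cannot count as support for the pattern. With a term for group, limma called 909 genes higher and 600 lower in these libraries. Ucp2, a mitochondrial carrier, stood at 38.8 and 40.43 FPKM in them against 7.908 to 11.74 in the other 4, and Angptl4, a lipase inhibitor, at 25.66 and 21.52 against 5.094 to 7.683. The mitochondrial transcript mt-Nd3 stood at 52.23 and 38.62 FPKM against 11.65 to 15.68, mt-Atp6 at 10.97 and 8.682 against 2.859 to 3.787, and Gm42418 at 87.23 and 178.5 against 33.32 to 54.63. Ptgs2, the inducible cyclooxygenase, had 182 and 113.8 FPKM against 41.83 to 94.29. Genes of the ATF4 and unfolded protein responses were lower in the libraries numbered 3 by a median of -0.23 in each group (camera adjusted p = 4.38e-09, adjusted p = 0.46 with an estimated correlation). Epithelial markers were lower by -0.24 with GFP-Rgnef and -0.37 without (camera adjusted p = 3.51e-07, adjusted p = 0.54 with an estimated correlation), and genes of the G2 and M phases by -0.07 and -0.16 (camera adjusted p = 6.06e-06, adjusted p = 0.58 with an estimated correlation). NRF2 targets were higher, by 0.37 and 0.18 (camera adjusted p = 4.03e-10, adjusted p = 0.54 with an estimated correlation), and so were mitochondrially encoded transcripts, by 0.22 and 0.04 (camera adjusted p = 0.00733, adjusted p = 0.58 with an estimated correlation).

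Sequencing depth as the source of this pattern was argued against by the depth of library 3, which differed from the mean of libraries 1 and 2 by -0.95 megareads in the knockout group and by 0.82 megareads in the GFP-Rgnef group. The deviations of both libraries correlated at 0.55 across genes, which are not independent replicates, and still at 0.52 after the median of genes of like GC content and length was removed, against GC content and length as the whole cause. A shared culture or preparation day and a difference in RNA quality could give such a pattern and stay open, untested, because the labels name neither.

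For chromosomes 7 and 9, a different copy number of whole chromosomes is a candidate explanation: 98.6% of windows of 20 neighbouring genes on them lay above 0.066, the 95th percentile of windows on the other autosomes. GC content and length were argued against by an excess of 0.318 after matching on both (0.305 before), and chance deviation of single libraries by a gap of at least 0.204 between the groups' libraries, where the largest range within a group was 0.056. Chromosomes 7 and 9 were picked for their medians in these same values, so a difference between the groups was given beforehand. The windows and libraries show only that it was spread along both chromosomes and did not rest on single libraries. A gain in the knockout cells and a loss in the GFP-Rgnef cells stay open, as no reference line was analysed here, and so does an effect of Rgnef on these chromosomes' genes. No DNA was measured, so the copy number itself remains a hypothesis.

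NRF2 targets were lower also with only the libraries numbered 1 and 2 (median -0.433, camera adjusted p = 4.07e-12 with the preset correlation). The difference thus did not rest on the libraries numbered 3. These were higher for this list in both groups (by 0.37 and 0.18), so this outcome was largely given beforehand. The camera call over all 6 libraries was lost with an estimated correlation (adjusted p = 0.51), which was not computed for the libraries numbered 1 and 2 alone. Reads shared between glutathione transferase copies were argued against by a median of -0.434 over the 30 members without those genes. Keap1, the inhibitor of NRF2, lies on chromosome 9 and differed by 0.112 (SE 0.088, limma adjusted p = 0.46), so a higher Keap1 dose could not be told apart from none. An effect of Rgnef stays open, untested, as the groups also differ in the lentivirus and may differ as clones.

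Of the 10 splits of the 6 libraries into 3 and 3, the real one called 1539 genes and the highest other called 0, so that 1 split reached the real number. For lists, 4 splits reached the real number of 10, the real one included, and the highest other called 11. With 10 splits a share under 0.05 cannot be reached.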
